A study of Rattus norvegicus with 24 samples.

How the data were processed

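The series covers 24 samples of Sprague-Dawley rat neural stem cells and cells differentiated from them without or with vitamin C. The 6 RNA-seq libraries, 2 per group, were analysed; the other 18 samples (MBD-seq, hMeDIP-seq, NFI ChIP-seq and inputs) were not analysed here. The replicate 1 libraries of the differentiated cells carry a D4 label and those of replicate 2 a D5 label, and nothing in the labels says whether replicates are separate cultures or animals, so p-values measure the spread between these samples.

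The deposited values are CPM per gene, scaled by the authors. Their processing notes name STAR 2.5.1, edgeR 3.12.1, CASAVA 1.7, Bowtie2 2.1.0, HOMER 4.9.1 and deepTools 2.4.2 and the rn5 build, without saying which served the RNA-seq; the read counter, annotation and gene filter are not stated. RNA libraries were made with a TruSeq kit. Every value was a whole multiple of 1 step per library (relative tolerance 1e-06), so whole reads were recovered by dividing by that step. Recovered reads over the 12187 genes were 4811094, 5372983 and 6641721 in replicate 1 (stem cells, without and with vitamin C) and 10299321, 11210514 and 13184601 in replicate 2, so depth followed the replicate number. The reads listed were 60.2% to 67.7% of the total the authors scaled by. Every gene reached at least 0.967 CPM in some library. No coordinates are given. A count of 0 allows up to 3 reads, from 0.140 CPM in the deepest library to 0.378 CPM in the shallowest. These limits and the intervals on read ratios cover counting error only. Intervals on list medians and on a share of genes cover the spread among genes, which are not independent.

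Genes with at least 1 CPM in at least 2 libraries were tested, 11823 in all. The test was limma 3.58.1 (trend, two-sided) on log2(CPM + 0.5) in R 4.3.3, with 3 groups in 1 fit, 3 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05. With 2 libraries against 2 an exact permutation test cannot go below p 0.333, so none was used for single genes. Lists of genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the 38 of 41 lists with at least 4 members tested. Camera with an estimated correlation and fry served as checks; fry tests whether members move, on balance, one way. The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined.

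The rule named, per comparison and side, the 6 genes of smallest p with non-overlapping groups and a mean of at least 5 CPM in the higher group when fewer than 3 passed the test, up to 2 members of highest mean CPM per list, and a fixed panel of genes; some genes under this rule are not reported here. Non-overlapping groups were found for 16.0% of genes between cells with and without vitamin C. Against stem cells the share was 26.9% for cells without vitamin C and 27.4% for cells with it. Chance gives 33.3% if libraries are interchangeable. Replicate differences were shared across groups, which makes groups overlap, so these shares cannot be read against that value. Genes named beyond the rule are said to have been chosen after their values were seen.

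Libraries with and without vitamin C share a replicate number and a day label, so a fit with a replicate term is given beside that comparison; it leaves 2 residual degrees of freedom. Deviations of a replicate from its group mean correlated across genes at 0.914 between cells with and without vitamin C. For comparisons with stem cells only the number is shared, and that check, paired counts and list calls are in the closing section.

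Alternatives were pseudocounts of 0.1 and 2, no filter, at least 5 CPM in 2 libraries, median-of-ratios and quantile rescaling, the replicate term, no trend, a minimum fold of 1.5 (limma treat), fits of 2 groups, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library. DESeq2 with the replicate term, the correlations across replicates, the test of the replicate term and the genes called in both comparisons by DESeq2 were added after the data were seen. With a library left out, the lone library of its group was assumed to vary like the other groups, and the replicate difference enters the comparison.

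The code was tested on simulated counts with the replicate difference of these libraries, a dispersion of 0.05 and known changes between cells with and without vitamin C. Limma without pairing, run on 12099 genes, recovered 0 of 67 genes changed 2-fold, 0 of 67 changed 4-fold and 0 of 66 changed 8-fold; with pairing it recovered 17, 65 and 66, with 5 unchanged genes called. DESeq2, run on 12187 genes, recovered 4, 30 and 50 without pairing and 17, 63 and 65 with it. Camera at the preset correlation called a list of 24 genes shifted by -0.7 (adjusted p 5.06e-16) and 0 of 200 random lists, and with an estimated correlation it did not call the shifted list (0.468). Simulated genes varied independently, so this does not test the preset against real correlation between genes.

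A second hypoxia list and 3 further lists were compared with 10000 random lists matched on expression in bins of 100 genes, and medians were resampled 10000 times for 95% intervals. Positions of the 3 further lists are not used, since the lists were chosen after the calls were seen and hold called genes. Lists whose medians went opposite ways in the replicates by at least 0.3 each were sought for the vitamin C comparison, and 0 of 38 did; the minimum was set after the data were available, and without it 16 did, 1 of them called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.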

Results

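Vitamin C is a cofactor of iron-dependent dioxygenases, among them the prolyl hydroxylases that mark HIF-1 alpha for degradation and the enzymes that oxidise 5-methylcytosine. Gene expression was compared in rat neural stem cells labelled D0, in cells differentiated from them without vitamin C, and in cells differentiated with vitamin C, with 2 RNA-seq libraries per group. The question was which genes differ between the differentiated cells with and without vitamin C, and how each differs from the stem cells. Expression is given in CPM (read counts scaled to a common library size), for the library of replicate 1 and then that of replicate 2, and differences are log2 values with the standard error (SE) of the limma fit over 2 libraries per group.

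The replicate sets differed more than the groups. Genes of microglia and macrophages were all higher in replicate 2, 20 of 20 members, with median log2 differences of 4.85 in stem cells, 5.85 without vitamin C and 5.91 with it. C1qa, chosen after its values were seen, was at 0, 0.349 and 0 CPM in the replicate 1 libraries of these groups and at 40.7, 134 and 80.5 CPM in replicate 2. Genes of fibroblasts, pericytes and meninges were higher in replicate 2 for 17 of 17 members, with medians of 5.24, 3.65 and 4.70, and Col1a1 stood at 39.1 CPM in stem cells of replicate 1 and 5968 CPM in replicate 2. Interferon response genes were also higher there, 20 of 20 members with medians of 2.8, 5.0 and 5.6. Oligodendrocyte lineage genes were lower in replicate 2 for 14 of 19 members, with medians of -1.11, -3.61 and -3.19. Replicate number took up 67.9% of the variation between libraries, group 21.0% and the remainder 11.1%. The replicate term of a limma fit with groups and replicate, tested after the data were seen, called 2971 of 11823 genes, 2061 higher and 910 lower in replicate 2. Camera on that term called the microglia (adjusted p 1.58e-13), interferon (2.33e-11) and fibroblast (1.21e-09) lists up and the oligodendrocyte list down (1.67e-07), but none of these 4 with an estimated correlation (0.471 for the first 3, 0.529 for the last). Fry called the microglia (0.0161), interferon (0.0342) and fibroblast (0.00597) lists and not the oligodendrocyte list (0.111). Values by replicate are given beside the differences between groups.

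**Figure D1:**
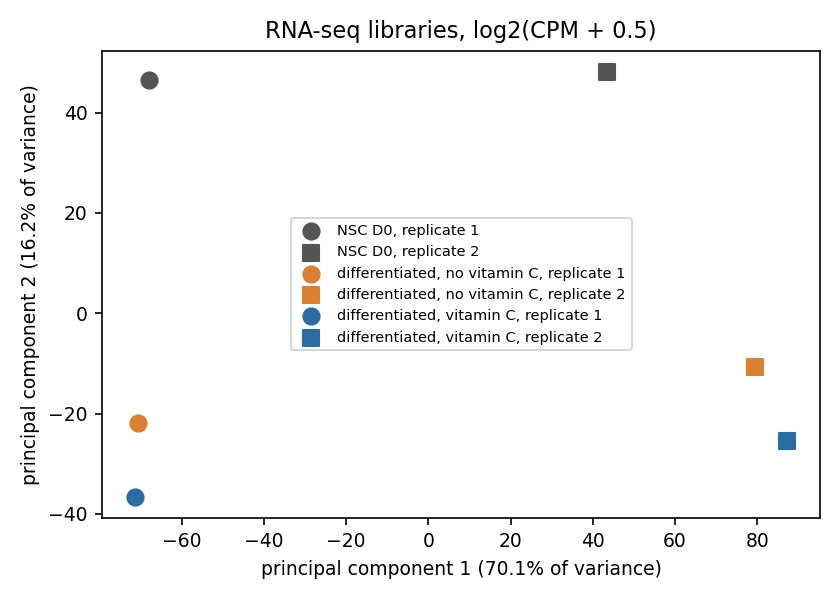
Principal components 1 and 2 of the 6 RNA-seq libraries, from log2 CPM, with colour for the group and marker shape for the replicate. Replicates separate on component 1, which holds 70.1% of the variance, and stem cells separate from differentiated cells on component 2, which holds 16.2%.

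Most genes of the hypoxia response list, which includes glycolytic enzymes, were lower with vitamin C than without it in both replicates. Ldha stood at 316 and 437 CPM without vitamin C and at 80.2 and 122 CPM with it, a log2 difference of -1.90 (SE 0.33). Tpi1 went from 308 and 340 CPM to 88.0 and 126 CPM, and the most abundant list members, Eno1 and Aldoa, differed by -0.90 (SE 0.26) and -0.97 (SE 0.30). Vegfa and Ankrd37, both chosen after their values were seen, were at 165 and 591 CPM against 76.7 and 196 CPM, and at 3.14 and 8.81 CPM against 0.383 and 1.55 CPM. The hypoxia response list fell with vitamin C in camera with a preset correlation between genes (adjusted p 2.71e-20 over 38 lists), but not with an estimated correlation (0.681) or with fry (0.993). With the replicates paired, fry came nearer to the threshold without passing it (adjusted p 0.0740), and camera with an estimated correlation did not pass (0.431). It had a median of -0.73 over 24 members, -0.66 in replicate 1 and -0.73 in replicate 2. In both replicates 18 members were lower and 3 higher. Over all genes tested, 26.4% were lower and 30.0% higher with vitamin C in both replicates. Adjusted over the list alone, 2 members passed in limma and 14 with the replicates paired, while 0 passed over all genes tested in either fit. The call at the preset correlation held with pairing (8.38e-18) and without any 1 library; its adjusted p over all alternatives ran from 3.12e-21 to 0.993.

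Cholesterol synthesis and astrocyte genes were higher with vitamin C. All 21 cholesterol synthesis members were higher in both replicates, with a median of 0.81, 0.78 in replicate 1 and 0.63 in replicate 2. Hmgcs1 stood at 296 and 95.4 CPM without vitamin C and at 720 and 192 CPM with it. Among astrocyte genes, Gfap went from 101 and 224 CPM to 684 and 2072 CPM. Apoe went from 830 and 4491 CPM to 3384 and 5278 CPM, Sparcl1 from 826 and 2148 CPM to 1348 and 3581 CPM. Aqp4 and Agt, chosen after their values were seen, went from 385 and 687 CPM to 2322 and 2392 CPM and from 50.5 and 13.5 CPM to 324 and 73.5 CPM. Cst3, also chosen afterwards, went the other way, from 1237 and 713 CPM to 324 and 488 CPM. The astrocyte list rose with a median of 0.83 (adjusted p 3.00e-06, camera), 0.67 in each replicate, with 15 of 22 members higher and 2 lower in both, and its call held without any 1 library. Neither this list nor cholesterol synthesis (adjusted p 4.90e-13 at the preset) passed with an estimated correlation (0.681 for both). The cholesterol call was also lost without replicate 2 of the cells lacking vitamin C (0.279) and without replicate 1 of the cells given it (0.448). Over all alternatives the adjusted p ran from 3.06e-23 to 0.993 for cholesterol synthesis and from 3.06e-08 to 0.993 for astrocytes. Without replicate 1 of the cells lacking vitamin C, Apoe reversed to -0.088.

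Cytosolic ribosomal protein genes were slightly lower with vitamin C, 29 of 32 members in both replicates, with a median of -0.35 (-0.46 and -0.21 by replicate). Rplp0 went from 1007 and 692 CPM to 656 and 597 CPM, and Rps2 from 950 and 441 CPM to 743 and 419 CPM. Immediate early genes had a median of -1.24 in replicate 1 and of 0.03 in replicate 2, with 6 of 17 members lower and 1 higher in both. Jun was at 93.0 CPM without and 32.3 CPM with vitamin C in replicate 1, and at 110 and 103 CPM in replicate 2. Hedgehog signalling genes had a median of -0.74 (-0.69 and -0.60 by replicate) and were not called unpaired (adjusted p 0.0786). With the replicates paired they were called (0.00239), though not with an estimated correlation (0.587). The ribosomal list was called down (adjusted p 6.75e-16), also without any 1 library, but not with an estimated correlation (0.681) or fry (0.993). Immediate early genes were called down at 0.000241, but not with an estimated correlation (0.681) or fry (0.993), and reversed without replicate 1 of the cells given vitamin C (0.821).

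Smaller calls came from lists with medians nearer to 0 or with few members. Replication-dependent histones (4 members, 4 lower in both replicates, adjusted p 0.00622), p53 targets (median -0.27, 0.0127), JmjC histone demethylases (-0.11, 0.0127) and housekeeping reference genes (-0.12, 0.0251) were called down, and heat shock and ER chaperones (0.31, 0.0127) up. None passed with an estimated correlation (0.681 for histones, p53 targets and housekeeping genes, 0.685 for JmjC demethylases and 0.810 for chaperones), and each was lost or reversed without certain libraries. Without replicate 1 of the cells lacking vitamin C the adjusted p was 0.320 for histones, 0.595 for JmjC demethylases, 0.826 for chaperones and 0.595 for housekeeping genes. Without replicate 2 of the cells given vitamin C it was 0.284 for histones, 0.421 for chaperones and 0.284 for housekeeping genes, and JmjC demethylases reversed (0.637). The p53 call was lost without replicate 2 of the cells lacking vitamin C (0.419) and without replicate 1 of the cells given it (0.827), and the housekeeping call also without the latter (0.0920). With pairing the housekeeping list did not pass (0.0544), while lower expression was called for fibroblast, pericyte and meninges genes (0.00133, median -0.47), collagens and their hydroxylases (0.00239), Hox genes (0.0449), BMP and TGF beta targets (0.0477) and pan-neuronal genes (0.0477). These 5 did not pass with pairing and an estimated correlation (0.587, and 0.796 for pan-neuronal genes), nor did any other list called with pairing (smallest adjusted p 0.431). Medians had opposite signs in the replicates for collagens (0.22 and -0.45), Hox genes (-0.65 and 0.17) and pan-neuronal genes (-0.21 and 0.03). In all, 10 of 38 lists were called for vitamin C, 3 up and 7 down; 15 were called with pairing and 0 with an estimated correlation or with fry.

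Lists of nuclear factor I genes (adjusted p 0.829), DNA methylation and demethylation enzymes (0.812, 19 members), midbrain dopamine lineage genes (0.419), cell cycle genes (0.846) and oligodendrocyte lineage genes (0.829) were not called for vitamin C. For oligodendrocyte genes the median was 0.16 while the mean was -0.08. Of 19 members 9 were higher and 8 lower in both replicates, so the missing call does not show that members were unchanged. Nfia stood at 62.0 and 58.0 CPM without and 65.0 and 53.4 CPM with vitamin C, Nfib at 26.5 and 17.4 CPM against 35.5 and 15.1 CPM, Nfic at 21.2 and 36.5 CPM against 19.2 and 34.7 CPM, and Nfix at 87.7 and 83.5 CPM against 102 and 85.5 CPM. Th rested on few reads in replicate 1, with 2 reads without and 16 with vitamin C, a CPM ratio of 6.58 (exact 95% interval 1.55 to 59.0). In replicate 2 it had 63 and 1384 reads, or 3.38 and 64.8 CPM, a ratio of 19.1 (14.9 to 25.1). Both intervals cover read counting in 1 library against 1, not the spread between libraries. Th was not called for vitamin C in limma or DESeq2, with or without pairing. Nr4a2 stood at 5.93 and 7.52 CPM against 4.50 and 11.1 CPM. Sox2, Map2 and Olig2 were at 452 and 343, 212 and 137, and 765 and 61.6 CPM without vitamin C, and at 455 and 332, 206 and 121, and 485 and 55.8 CPM with it.

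For single genes, the smallest p on the higher side belonged to Itga6, Fmo1, Slc14a1, Scd1, Necab3 and Slc12a4, and on the lower side to Col5a3, Ldha, Tpi1, Narf, Eno1 and Aldoa; none passed the limma test. Itga6, an integrin subunit, was higher by 1.16 (SE 0.21), 1.24 in replicate 1 and 1.07 in replicate 2. Fmo1, a flavin monooxygenase, was higher by 3.05 (SE 0.59). Col5a3, a collagen chain, differed by -1.54 (SE 0.26). The limma test called 0 of 11823 genes, with 62 at an unadjusted p under 0.05 where chance gives 591, and edgeR called 0, with 67. DESeq2 called 6, 3 higher and 3 lower. With replicates paired, limma called 0 (404 unadjusted), edgeR 0 (441 unadjusted) and DESeq2 32, 23 higher and 9 lower. All 32 went in the same direction in both replicates, which a fit on 2 pairs favours when it calls genes. The paired DESeq2 fit was chosen after the data were seen. Its adjusted p was 2.74e-10 for Ldha, 2.12e-06 for Tpi1, 3.12e-05 for Fmo1 and 0.0488 for Gfap, each of which had 1.00 in limma. It also called Mobp, chosen after its values were seen, at 167 and 3.98 CPM without and 2.77 and 0 CPM with vitamin C. On simulated data with the same replicate difference, limma without pairing recovered 0 of 66 genes changed 8-fold for this comparison, so its count of 0 does not bound how many genes differ. Paired limma recovered 65 of 67 genes changed 4-fold and 66 of 66 changed 8-fold there, at a simulated dispersion of 0.05. The libraries varied somewhat more than that, with a biological coefficient of variation of 0.268 in the paired edgeR fit. That coefficient is the square root of a dispersion, so 0.268 and 0.05 are on different scales. Paired DESeq2 called Fmo1 at 3.23, so the 0 calls of paired limma do not exclude changes of this size.

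**Figure D2:**
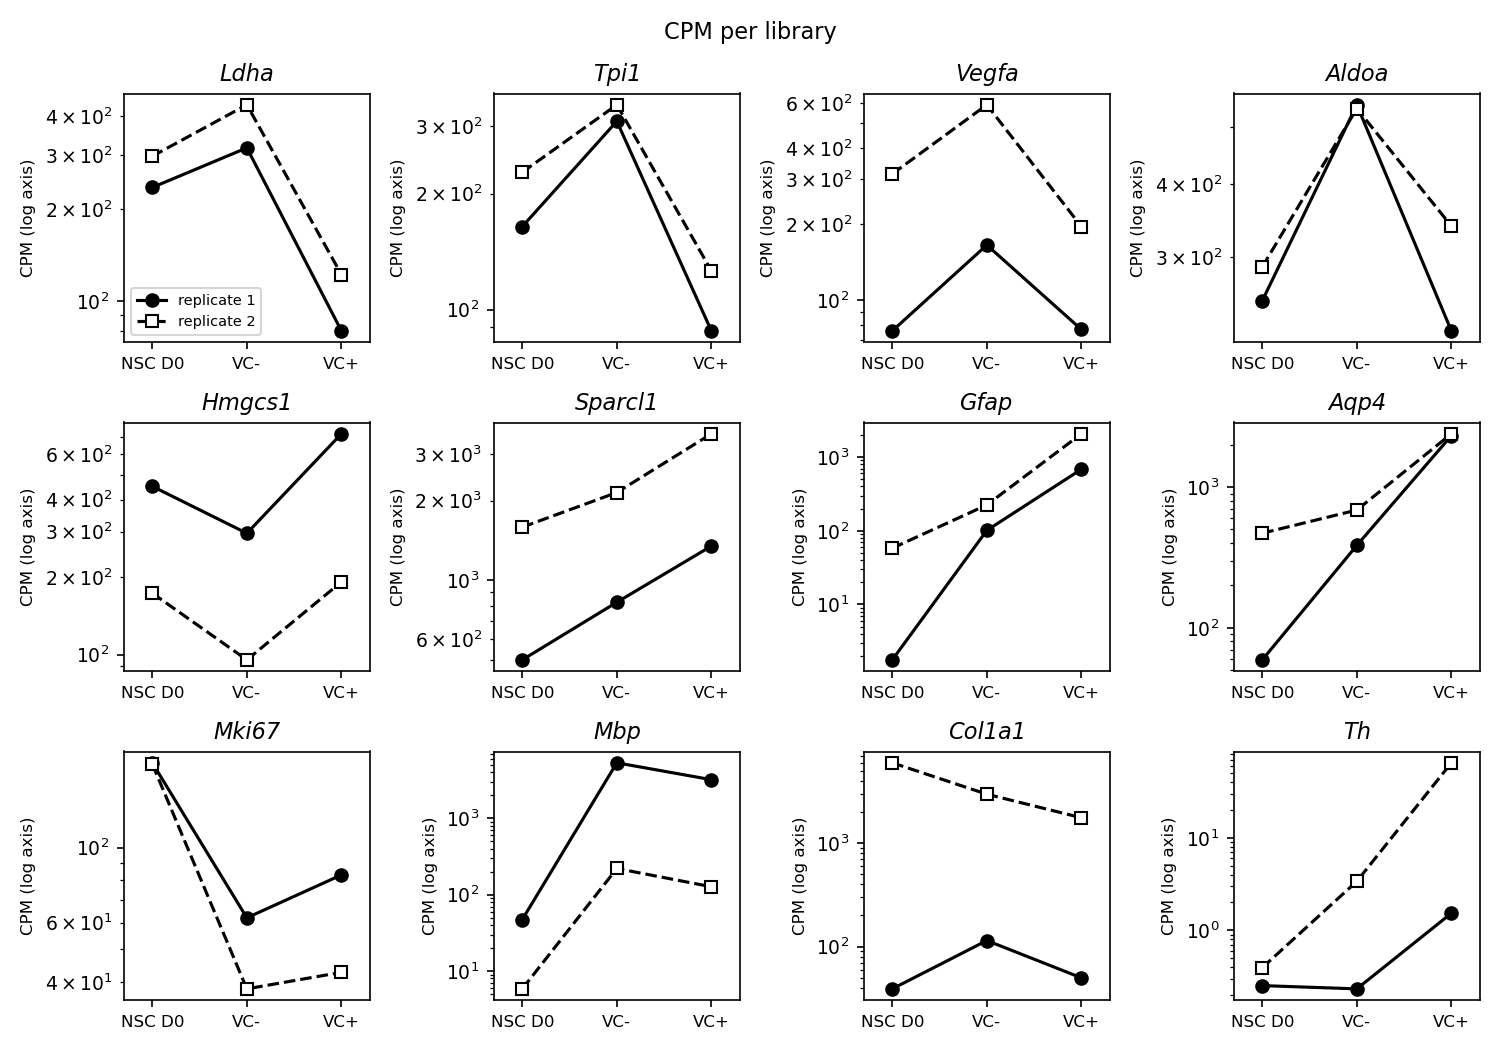
CPM per library on a log axis for 12 genes, with 1 line per replicate joining stem cells (NSC D0), cells differentiated without vitamin C (VC-) and cells differentiated with it (VC+). Ldha, Tpi1, Vegfa and Aldoa were lower, and Hmgcs1, Sparcl1, Gfap and Aqp4 higher, with than without vitamin C in both replicates, while Col1a1 and Mbp were separated by replicate.

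Differentiation without vitamin C went with lower proliferation genes and higher hypoxia-induced and oligodendrocyte genes than in stem cells. Mki67 stood at 179 and 177 CPM in stem cells and at 62.0 and 38.1 CPM without vitamin C, and Top2a at 241 and 159 CPM against 90.0 and 54.3 CPM. Cell cycle and DNA replication genes had a median of -1.18, -0.94 in replicate 1 and -1.35 in replicate 2, with 31 of 34 members lower in both. Hypoxia response genes were higher for 20 of 24 members, with a median of 0.69 (0.51 and 0.81 by replicate), and Aldoa went from 253 and 289 CPM to 547 and 539 CPM. Cholesterol synthesis genes were lower for 20 of 21 members, with a median of -0.90 (-0.51 and -1.16). The hypoxia and cholesterol lists went the other way for vitamin C. That comparison shares the libraries without vitamin C, with opposite sign, so the opposite medians are not independent findings. Oligodendrocyte lineage genes had a median of 2.18, with 3.33 in replicate 1 and 1.04 in replicate 2, and Mbp went from 47.3 and 5.85 CPM to 5346 and 221 CPM. Pan-neuronal genes had a median of 0.62 (1.19 and 0.26), with Tubb3 at 10.5 and 45.7 CPM in stem cells and 46.9 and 91.0 CPM without vitamin C. Camera called the cell cycle (adjusted p 1.87e-20), hypoxia (2.28e-07), cholesterol (3.66e-07), oligodendrocyte (4.15e-06) and pan-neuronal (4.45e-05) lists. None of these 5 passed with an estimated correlation, which gave 0.908 for the cell cycle, hypoxia and pan-neuronal lists and 0.945 for the cholesterol and oligodendrocyte lists. The cell cycle and hypoxia calls held without any 1 library; the others were lost without replicate 2 (cholesterol, 0.165) or replicate 1 (oligodendrocyte, 0.249) of the cells lacking vitamin C, or without replicate 1 of the stem cells (pan-neuronal, 0.119).

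Immediate early genes were higher without vitamin C than in stem cells, and Hedgehog, ribosomal and stem cell marker genes were lower. Camera called these lists, and NRF2 targets up, at the preset correlation but not with an estimated one, which gave an adjusted p of 0.908 for Hedgehog genes and stem cell markers, 0.945 for immediate early genes and 0.998 for ribosomal genes and NRF2 targets. The immediate early median was 1.02 (adjusted p 0.00272), 1.24 and 1.19 by replicate, with 12 of 17 members higher in both. This list was called down for vitamin C, in a comparison that shares the libraries without it. Hedgehog genes had a median of -0.55 (0.0182), -0.26 and -0.69 by replicate, with Ptch1 at 141 and 337 CPM in stem cells and 138 and 105 CPM without vitamin C. Ribosomal genes had a median of -0.18 (0.0182), -0.084 and -0.24 by replicate, and NRF2 targets of 0.32 (0.0420), 0.18 and 0.39 by replicate. Stem and progenitor markers had a median of -0.37 (0.0325), -0.13 and -0.36 by replicate, with Nes at 159 and 116 CPM against 81.6 and 53.5 CPM. Without replicate 1 of the stem cells the immediate early (0.0803) and ribosomal (0.793) calls were lost, and without replicate 2 of the stem cells the Hedgehog (0.579), stem cell marker (0.492) and NRF2 (0.515) calls. Without replicate 1 of the cells lacking vitamin C the Hedgehog call was lost (0.133), and without replicate 2 of them the stem cell marker (0.142) and NRF2 (0.379) calls, while ribosomal genes reversed (0.870). Of 38 lists 10 were called, 5 up and 5 down, and 0 with an estimated correlation or with fry.

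The genes of smallest p against stem cells were Igsf11, Syde2, Fnbp1, Spire2, Pfkp and Phyhipl on the higher side and Sorcs1, Itga6, Col5a3, Gria3, Akap6 and Siae on the lower; none passed the limma test. Igsf11, an adhesion molecule, was higher by 2.15 (SE 0.20), and the sorting receptor gene Sorcs1 differed by -2.82 (SE 0.29). Itga6 and Col5a3 differed by -1.66 (SE 0.21) and -1.96 (SE 0.26). In limma 0 genes were called, with 382 at an unadjusted p under 0.05 where chance gives 591. EdgeR called 0, with 380 where chance gives 599, and DESeq2 called 63, 18 higher and 45 lower. The replicate difference stays in the spread of these unpaired fits, so their counts do not bound how many genes differ. Counts with a replicate term are in the closing section.

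Differentiation with vitamin C went with lower proliferation genes and higher astrocyte and oligodendrocyte genes than in stem cells. Cell cycle genes had a median of -1.09 (-1.14 and -1.20 by replicate), with 32 of 34 members lower in both, and Mki67 stood at 83.1 and 42.7 CPM. Ribosomal genes had a median of -0.51 (-0.56 and -0.40), with 31 of 32 members lower in both. Oligodendrocyte lineage genes had a median of 2.37 (3.22 and 1.18), with Mbp at 3212 and 127 CPM. Astrocyte genes had a median of 0.93 (0.71 and 0.80), and Gfap went from 1.77 and 57.9 CPM in stem cells to 684 and 2072 CPM. Hedgehog genes had a median of -0.65 (-0.66 and -1.22), p53 targets of -0.60 (-0.82 and -0.63) and Notch genes of -0.73 (-0.28 and -1.06). Stem and progenitor markers had a median of -0.49 (-0.16 and -0.42), with Nes at 35.3 and 32.5 CPM. NRF2 targets had a median of 0.21 with opposite signs in the replicates (-0.12 and 0.74), where 8 of 23 members were higher and 1 lower in both. Camera called cell cycle (adjusted p 1.87e-18), ribosomal (1.16e-12), oligodendrocyte (3.46e-05), Hedgehog (0.000567), p53 (0.00201), astrocyte (0.00378), pan-neuronal (0.00841, medians 0.76 and 0.26 by replicate), stem cell marker (0.0109), Notch (0.0179), histone (0.0215, medians -1.11 and -1.08), collagen (0.0307, medians -0.36 and -1.07) and NRF2 (0.0307) lists. None of these 12 passed with an estimated correlation (smallest adjusted p 0.724) or with fry (0.633). The hypoxia and cholesterol lists were not called (0.530 and 0.656), with members going both ways. Of 24 hypoxia genes 10 were higher and 8 lower in both replicates, and the cholesterol medians were 0.40 and -0.48 by replicate.

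The cell cycle and ribosomal calls with vitamin C held without any 1 library. Without replicate 2 of the stem cells the calls were lost for Hedgehog (0.118), p53 (0.133), stem cell marker (0.261), Notch (0.295) and NRF2 (0.306) genes, and collagens reversed (0.306). Without replicate 1 of the stem cells they were lost for astrocyte (0.125), pan-neuronal (0.483) and histone (0.325) genes. Without replicate 1 of the cells given vitamin C they were lost for oligodendrocyte (0.309), p53 (0.143) and collagen (0.770) genes, and without replicate 2 of them for histones (0.157), while NRF2 targets reversed (0.593). Of 38 lists 12 were called, 4 up and 8 down, and 0 with an estimated correlation or with fry. Among single genes, those of smallest p were Igsf11, Slc14a1, Fmo1, Syde2, Pfkp and Slc25a34 on the higher side and Col5a3, Sorcs1, Akap6, Meis1, Nes and Itga8 on the lower; none passed the limma test. Igsf11 was higher by 2.66 (SE 0.20) and Col5a3 differed by -3.50 (SE 0.26), each at an adjusted p of 0.228. In limma 0 genes were called, with 507 at an unadjusted p under 0.05 where chance gives 591. EdgeR called 0, with 506 where chance gives 599, and DESeq2 called 133, 55 higher and 78 lower. These unpaired counts likewise do not bound how many genes differ, and the balance of directions turned with a replicate term (closing section).

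**Figure D3:**
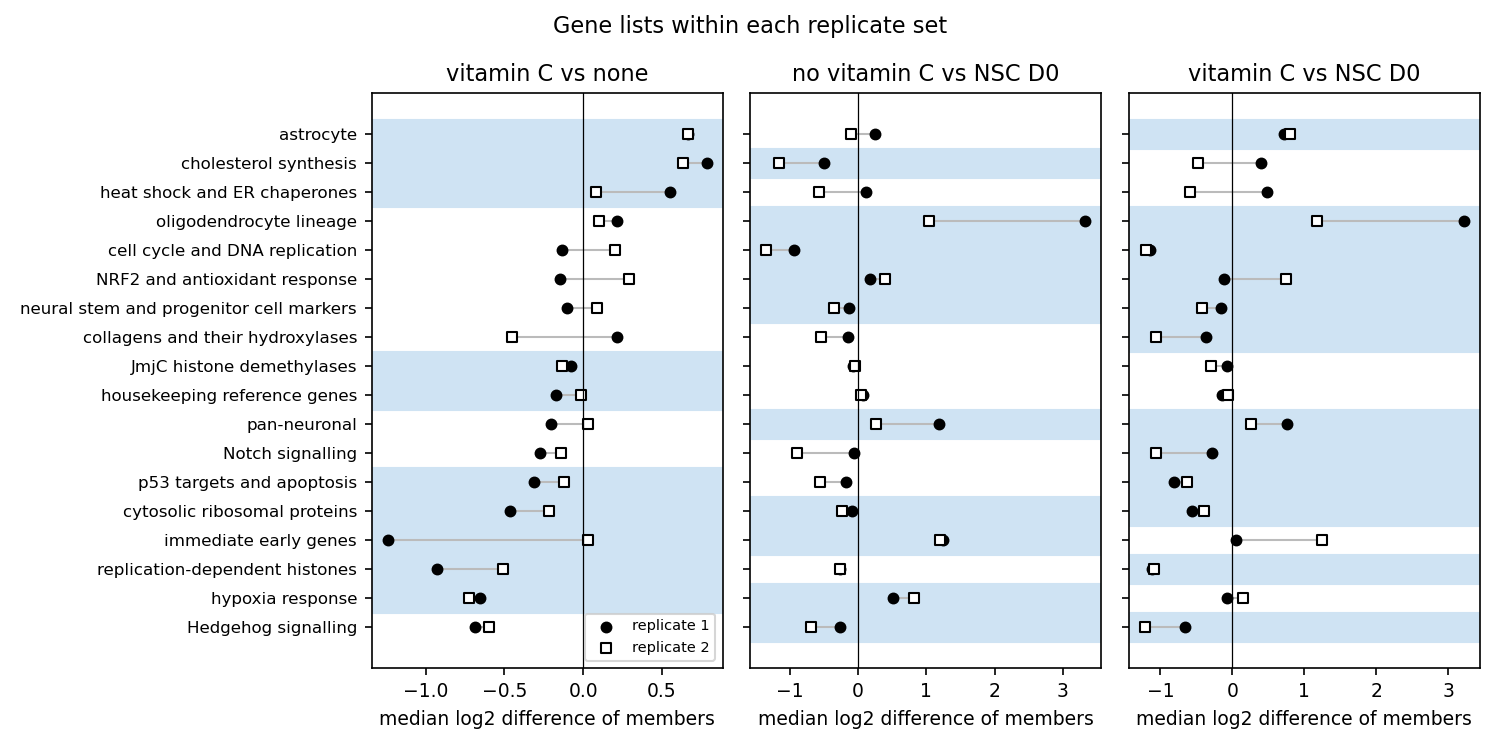
Median log2 difference of the members of each gene list called in at least 1 comparison, with filled circles for replicate 1, open squares for replicate 2 and shading where the list was called. Hypoxia response genes were lower with than without vitamin C in both replicates (-0.66 and -0.73) and higher without vitamin C than in stem cells (0.51 and 0.81). Both comparisons use the libraries without vitamin C, so these are not independent findings.

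Across 11823 genes, which are not independent replicates, the change from stem cells without vitamin C and the change with it correlated at r 0.85, and shared stem cell libraries alone gave 0.50 in 100 simulations. Taken across replicates, so that no library was shared, r was 0.23 and 0.31. The vitamin C difference and the change without vitamin C, which share libraries with opposite sign, correlated at -0.03, where unchanged groups gave -0.50, and at 0.06 and -0.03 across replicates. The covariance was -0.0083 against a simulated -0.0675 with the paired spread and -0.336 with the unpaired spread. The simulations drew the libraries independently of each other. In the data, deviations from group means correlated at 0.914 between cells with and without vitamin C. With stem cells they correlated at 0.730 for cells without and 0.688 for cells with vitamin C. The simulated values leave out this sharing, so no relation is read from a distance to them. Limma called no gene in both comparisons, so the planned share of genes with the same direction had no value. Leaving out 1 library at a time gave -0.67 to 0.14 for the latter relation and 0.49 to 0.92 for the former. The replicate difference then enters the changes, so these ranges cannot tell whether the pooled values depend on single libraries.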

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

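DESeq2 with the replicate term and the correlations across replicates were chosen after the data were seen. The count of genes called was 0 in limma and in 18 of 20 alternatives for each comparison, leave-outs included (0 to 0). Limma without pairing recovered 0 of 66 simulated 8-fold changes for vitamin C, so its zeros are no sign of stability. DESeq2 called 6 genes for vitamin C, 63 for cells without it against stem cells and 133 for cells with it against stem cells, and with the replicate term 32 (23 higher, 9 lower), 455 (187 higher, 268 lower) and 768 (422 higher, 346 lower). For cells with vitamin C against stem cells the balance of directions thus turned from 55 higher and 78 lower without the term. With the term, limma and edgeR still called 0 genes against stem cells, with 1550 and 1669 at an unadjusted p under 0.05, where chance gives 591 and 599, without vitamin C and 1885 and 1990 with it (smallest adjusted p 0.157 and 0.103, then 0.0550 and 0.0555). Stem cells share only a number with the others, and deviations from group means correlated at 0.730 with cells without and 0.688 with cells given vitamin C. The smaller replicate spread left by the term is part of its construction; for DESeq2 without it the cause was not tested.

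With an estimated correlation or with fry, 0 lists were called in each comparison. With the replicate term 15, 18 and 17 were called, in the order above. Gained without vitamin C against stem cells were microglia (0.00128), collagen (0.00771), interferon (0.0130), Notch (0.0254), ependyma (0.0272), p53 (0.0272), BMP (0.0365) and Wnt (0.0407) lists, and with vitamin C interferon (0.00112), Wnt (0.0110), ependyma (0.0123), polycomb (0.0448) and microglia (0.0465) lists. With the term and an estimated correlation 0 were called (smallest 0.431, 0.709 and 0.670). Leaving out 1 library gave 11 to 20, 11 to 15 and 12 to 20. For vitamin C, estimated correlation and fry gave 0.681 and 0.993 for the hypoxia, ribosomal and cholesterol lists, which without 1 library ran from 7.68e-19 to 0.000366, 1.73e-14 to 0.0213 and 3.06e-23 to 0.448. For cells without vitamin C against stem cells they gave 0.908 and 0.970 for cell cycle and hypoxia and 0.945 and 0.970 for cholesterol (4.07e-14 to 0.165 without 1 library). For cells with vitamin C against stem cells they gave 0.724 and 0.633 for cell cycle, 0.729 and 0.633 for ribosomal and 0.877 and 0.985 for oligodendrocyte genes (8.79e-14 to 0.309 without 1 library). Estimated correlations rise with a replicate difference that members share, but the cause was not tested.

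Reversed directions came from leaving out 1 library, which leaves a replicate unbalanced: Apoe (-0.088) and Fos (0.044) without VC- replicate 1, Fos (0.14) and immediate early genes (0.821) without VC+ replicate 1, JmjC demethylases (0.637) and NRF2 targets (0.593) without VC+ replicate 2, ribosomal genes without vitamin C against stem cells (0.870) without VC- replicate 2, and collagens (0.306) without D0 replicate 2. Over all such fits Apoe ran from -0.088 to 2.35, Fos from -1.06 to 0.14, and the adjusted p from 6.60e-08 to 0.821 for immediate early genes, 7.10e-05 to 0.637 for JmjC demethylases, 2.67e-05 to 0.870 for ribosomal genes, 2.80e-05 to 0.593 for NRF2 targets and 3.09e-07 to 0.770 for collagens. Among the smaller list calls, quantile normalization ended those of histones (0.0944 for vitamin C, 0.0909 for cells with it against stem cells), collagens (0.0846), and ribosomal (0.359) and stem cell marker genes (0.0585) without vitamin C against stem cells. A minimum of 5 CPM ended those of NRF2 targets (0.0515), Notch genes (0.0512) and collagens (0.0517), and the replicate term that of housekeeping genes (0.0544); the cause was not tested. Of 58 gene values, 56 kept their direction in every alternative run. Many were named because their groups did not overlap, or after their values were seen, so this count is no sign of stability. Sizes moved more for vitamin C: without 1 library Sparcl1 ran from 0.017 to 1.43, Hmgcs1 from 0.19 to 2.09 and Vegfa from -2.27 to -0.43.

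DESeq2 with the replicate term called 12 genes both for vitamin C and without it against stem cells, 6 in the same and 6 in the opposite direction. The shared libraries favour opposite directions without any effect (simulated r -0.50 with independent libraries). No such value was made for this split, so no relation is read from it. The relation of the vitamin C difference to the change without it moved from -0.03 to between -0.67 and 0.14 without 1 library. That of the changes from stem cells moved from 0.85 to between 0.49 and 0.92, and to 0.23 and 0.31 across replicates, where no library is shared. With 1 library left out the replicate difference enters the changes. Those ranges therefore cannot tell whether the pooled values depend on single libraries.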

Other observations

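Chosen after the result was seen were the tests on cell type lists, day labels and cell composition below, the second fibroblast and microglia lists, and the lists of cilium, FGF feedback and astrocyte reactivity genes.

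The hypoxia response list was lower with vitamin C by a median of -0.73. Scaling of the libraries is argued against, since the median after quantile normalization was -0.77 (95% bootstrap interval -0.98 to -0.43). A general lowering of hypoxia-induced genes predicted that a second list, written before its median was seen and sharing 0 genes with the first and 2 with other lists, would lie under the 2.5 percentile of matched random lists. It lay at percentile 0.01, with a median of -0.22 (-0.42 to 0.11) over 25 genes, 14 lower and 6 higher in both replicates, and medians of -0.05 in replicate 1 and -0.24 in replicate 2. This is consistent with a general lowering, of smaller size than in the first list and with an interval that includes 0; random lists do not share regulation as members of a list do, so their spread may be too narrow a yardstick. Loss of a cell type remains open: the lowest median of 12 cell type lists was -0.47 (-0.74 to -0.25), for fibroblasts, pericytes and meninges, and the lower ends of 2 lists reached the hypoxia median. By replicate the hypoxia medians were -0.66 and -0.73. Without vitamin C, fibroblast genes were higher in replicate 2 by a median of 3.65. The fall was thus of similar size where fibroblast genes were scarcer, though each replicate holds 1 library per group. Oxygen and HIF protein were not measured in these libraries.

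Replicate 2 differed from replicate 1 in fibroblast and microglia genes. Depth is argued against, since after thinning every library to 4811094 reads the lowest group median of the fibroblast list was 3.78, and 3.65 before. The D4 and D5 labels are argued against as the whole cause, since the stem cell libraries, both labelled D0, differed by 5.24 (2.14 to 5.99). A larger share of fibroblast-like and microglial cells in the replicate 2 cultures may contribute. Of 45 genes in second fibroblast and microglia lists, with none from the fixed lists, 95.6% were higher in replicate 2 in all 3 groups (exact 95% interval 84.9% to 99.5%), against 32.5% of all genes tested. Members had to pass the filter on CPM, and several were at 0 CPM in every replicate 1 library, so they passed through replicate 2 alone. The lists were also written after markers of these cell types were seen to be higher there. The share therefore cannot decide on this explanation. Lyz2 and Fstl1 were chosen after their values were seen. Lyz2 was at 0.504, 0.814 and 0.191 CPM in replicate 1 and 543, 886 and 643 CPM in replicate 2, and Fstl1 at 97.6, 51.3 and 55.1 CPM against 771, 415 and 252 CPM. A different state of the same cells is not excluded. Of the 17 fibroblast and 20 microglia genes 0 are in another list, and 4 and 0 of them reached 10 CPM in replicate 1 stem cells. The day labels are the one difference between replicates that the labels give; they may still add to the difference in the differentiated cells.

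Genes fed back on by FGF and ERK signalling had a median of -0.52 with vitamin C, with 12 of 17 lower in both replicates and 0 higher, and of -0.67 without and -1.05 with vitamin C against stem cells. These are values without a test, since this list and the next 2 were chosen after the calls were seen and hold called genes. Etv5, chosen after its values were seen, stood at 464, 133 and 61.2 CPM in replicate 1 stem cells, cells without and cells with vitamin C. In replicate 2 it stood at 226, 42.1 and 31.0 CPM. Motile cilium genes had a median of 0.56 with vitamin C (0.22 and 0.69 by replicate), with 14 of 20 higher in both replicates and 1 lower. Several were near 0 CPM in replicate 1. Odf3b, chosen after its values were seen, was there at 0.465 CPM without and 0.861 CPM with vitamin C. Against stem cells the cilium medians were 1.62 without vitamin C (0.47 and 2.34 by replicate) and 2.32 with it (0.49 and 3.16). Innate astrocyte reactivity genes had a median of 0.48 with vitamin C, 12 of 19 higher in both replicates and 0 lower, with medians of 0.25 in replicate 1, where several members were near 0 CPM, and 0.81 in replicate 2. Maob, the single tested member of the serotonergic and noradrenergic list, was at 16.4 and 45.1 CPM without vitamin C and at 33.7 and 66.8 CPM with it.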
